A study of Mus musculus with 12 samples.

How the data were processed

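Single-cell gene expression was measured in external genitalia of mouse embryos at 3 stages in both sexes, with 2 libraries in each of 6 groups and 12 libraries in all. Per the labels, the mice are of mixed B6/129 background with an Sf1cre driver, a Rosa-tdTomato reporter and a Runx1-eGFP reporter, and tissue was dissociated with Dispase II (1.2 U/mL), Collagenase IV and DNase. The deposited matrices hold raw UMI counts per gene and barcode after cell calling, which the submitters' processing notes ascribe to Cell Ranger with the mm10 genome; the file headers give Cell Ranger 3.0.1. The same notes name Seurat 4.0 for the authors' own clustering, which was not used here. The authors' 3 sheets of cluster names were left out, since they hold cluster numbers without barcodes. Whether the replicates are separate litters, pools or days is not given in the sources used here.

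The libraries held 5985 to 11817 barcodes and 72962849 to 108672746 UMIs (1063549657 in sum). Of 30830 rows, 30766 (99.8%) matched the GENCODE M21 annotation of GRCm38, and 2 rows are the reporters. Replicate libraries were checked for copies: the chi-square per degree of freedom between the 2 libraries of a group was 19.5 to 67.6, so none is a copy of another. Barcodes with under 500 detected genes (11871) or over 10% mitochondrial UMIs (6301) were left out, and 6580 likely doublets were removed (3.9 to 7.6% per library), scored by nearest neighbours among 2 simulated doublets per cell, at 0.8% per 1000 cells. Of 114412 barcodes 91708 were kept, with a median of 6051 to 11498 UMIs per cell in each library.

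Log-normalized counts of 2000 variable genes without sex-linked genes gave 30 principal components, 20 nearest neighbours and Leiden clusters at resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, seed 1). Clusters took the class with the best score over marker lists for 15 cell types, or none if no score reached -3.0. Counts were summed per library over the cells of a class. The mesenchyme sums hold 44959317 to 78624066 UMIs per library, the epithelium sums 1147876 to 2937755 (at least 92 cells) and the blood endothelium sums 1648774 to 3981460 (at least 52 cells). These 3 classes were compared as planned before the data were examined.

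Class sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit of the 6 groups, 6 residual degrees of freedom), with Benjamini-Hochberg adjusted p under 0.05 called. The sex comparison over all stages is the mean of the 3 male groups minus that of the 3 female groups; the stage comparisons average both sexes; the interaction is the E18.5 sex difference minus the E14.5 one. The sex-linked list is left out of the counts of genes, while other genes of the X and Y chromosomes stay in. DESeq2 1.42.0 was run as an alternative. Class shares were compared with exact permutations within strata. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of 1 comparison. There are 19 lists, written before the data were examined: sex-linked genes, androgen response, steroid receptors and enzymes, hedgehog, Wnt, BMP and FGF, genital tubercle patterning factors, extracellular matrix, smooth muscle contraction, cartilage and bone, S phase, G2M phase, epidermal differentiation, basal keratinocyte, urethral or endodermal epithelium, dissociation stress, hypoxia and glycolysis, interferon response, and the 2 reporter driver genes. A list with under 3 tested members was not tested.

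The rule for naming genes was also fixed before the data were examined. In the comparisons over all stages or both sexes it takes the 10 genes with the largest change in each direction among called genes that have at least 10 CPM in the higher group, move the same way in each stage or sex, and are neither sex-linked nor predicted. At single stages and for the interaction it takes 5. Rankings among the genes that the rule admits cover these genes only, not the members that it adds from lists. It adds up to 4 members per list with the smallest p, and always a set of genes chosen beforehand, among them Esr1, Pgr, Srd5a2, Runx1, Nr5a1, Shh and Hoxd13; some genes that the rule takes are not reported here. Nr5a1 had 1 to 10 UMIs per library over all kept cells and was not tested. Ratios with 1 to 3 UMIs on a side carry a 95% counting interval, and a floor is 3 counts.

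The pipeline was tested on simulated data, with 200 genes changed by log2 folds of 0.5, 1 and 2. For the mesenchyme sex comparison over all stages edgeR recovered 70.8%, 90.9% and 95.4% of them, with 13 false calls among 16329 genes. For the sex difference at E18.5 it recovered 47%, 80.6% and 81.5% (10 false calls), for the interaction 21.2%, 64.2% and 75.4% (12) and for E18.5 against E14.5 65.2%, 89.6% and 90.8% (5). In epithelium it recovered 12.3%, 54.5% and 93.8% for sex (10) and 4.5%, 47% and 86.4% for stage (5), and in blood endothelium 62.7%, 90.9% and 100% for sex (8). None had the wrong sign. Camera called the 1 changed list and 0 of the 9 unchanged ones in each of these. The simulated genes vary independently of each other, so this does not test camera on lists whose members move together.

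The alternatives tried were DESeq2, no TMM, no filter on low counts, at least 1000 genes per cell, a mitochondrial limit of 5%, no doublet removal, Leiden resolution 2, components centred per library, sums thinned to the smallest library, sums over all kept cells, the replicate number as a block, and leaving out each library. After the data were seen 3 more were added for mesenchyme: without clusters that have a marker of another class among their 10 leading genes, with chondrocyte-or-osteoblast-like cells, and without clusters led by cell cycle genes (at least 3 of the 10 leading genes). Other splits of the libraries into groups of the same size were fitted with an additive model (40 of the 462 possible for sex, 34 of 35 for stage, 1 of which could not be fitted). Figures were drawn with matplotlib 3.10.9. The reporter rows were counted but not compared.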

Results

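The series maps single cells of the external genitalia of mouse embryos before birth, across 3 stages and both sexes. Droplet-based 10x Genomics libraries were made from males and females at E14.5, E16.5 and E18.5 (embryonic days), with 2 libraries in each of 6 groups. The E14.5 libraries held 97378840 and 72962849 unique molecular identifiers (UMIs) in males and 106608747 and 108672746 in females. The E16.5 libraries held 83873177 and 82249217 in males and 84466963 and 78366543 in females, and the E18.5 libraries 92517583 and 100940457 in males and 77486193 and 78026342 in females. After filtering, 91708 of 114412 barcodes were kept, 4639 to 8791 per library. Xist, the RNA that silences an X chromosome, had 110533 to 143790 UMIs in each female library and 7 to 20 in each male library, and the Y-linked Ddx3y had 5095 to 7080 and 0. Where the 2 replicates of a group came from is not given in the sources used here. Every p-value below therefore measures the spread between these libraries only, and the intervals and floors given with single libraries cover counting error only. Values are estimate ± standard error on the log2 scale, or mean ± SD of 2 libraries, unless stated otherwise. Expression is given in CPM of the cell class.

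What cell types does this tissue hold, and do their shares move with stage or sex? The cells fell into 41 clusters, which were named from marker lists because the labels give no cell types. Mesenchyme, the connective tissue precursor, took 28 clusters and 76748 cells. Chondrocyte-or-osteoblast-like cells took 2 clusters and 4634 cells, and the 10 leading genes of the larger included the cartilage collagens Col9a1, Col9a3 and Col2a1 beside Agt, Krt8 and Pparg. Epithelium (2283 cells) was led by the basal keratins Krt14, Krt5 and Krt15, and erythroid cells (2938 cells) by the globin genes Hbb-bt and Hba-a2. The other named classes were blood endothelium (1119 cells), immune cells (1073 cells), glia (685 cells), mast cells (588 cells) and smooth muscle or pericytes (557 cells). The remaining 1083 cells stayed unnamed.

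Cartilage-like and contractile cells gained share with stage, while epithelial, erythroid, immune and mast cells lost share. Chondrocyte-or-osteoblast-like cells rose by 2.001 percentage points per embryonic day (adjusted p = 0.0111), from 0.00 ± 0.01% at E14.5 to 6.92 ± 0.32% at E16.5 and 8.01 ± 3.29% at E18.5 (mean ± SD, n = 4 libraries per stage). At E14.5, 3 of 4 libraries held 0 such cells, with floors (3 cells of the library) of 0.038%, 0.0647% and 0.0345%, and the other held 1 (0.01%, 95% interval 0 to 0.067%). The cartilage collagen Col2a1 was nonetheless read in E14.5 mesenchyme, where it was higher than at E18.5 (log2 fold change -1.49 ± 0.14, adjusted p = 7.21e-06). That direction turned when the chondrocyte-or-osteoblast-like cells were added to mesenchyme (0.39) and over all kept cells (0.34). Smooth muscle or pericytes rose by 0.182 points per day (adjusted p = 0.0044), from 0.22 ± 0.19% to 0.66 ± 0.07% and 0.94 ± 0.23%. Epithelium fell by 0.616 points per day (adjusted p = 0.02), from 4.16 ± 1.39% to 1.92 ± 0.60% and 1.69 ± 0.57%. Erythroid cells fell by 1.38 points per day (adjusted p = 0.0389), from 7.40 ± 6.54% to 1.67 ± 0.46% and 1.89 ± 1.47%. The E14.5 erythroid spread came with 1 library, male replicate 2, at 16.99% (95% interval 15.9 to 18.1%). Immune cells fell by 0.07 points per day and mast cells by 0.085 points per day, each with an adjusted p of 0.0389. The immune direction turned with a mitochondrial limit of 5% (0.027 points per day). Glia (0.053 points per day, adjusted p = 0.0673), blood endothelium (0.031, adjusted p = 0.688) and mesenchyme (0.212, adjusted p = 0.832) did not pass. These are exact two-sided permutation tests of stage within sex over 8100 arrangements, whose smallest possible p is 0.000247. Of the 9 classes 6 passed with all libraries, and 3 without E14.5 male replicate 2, E14.5 female replicate 2, E18.5 male replicate 1, E18.5 female replicate 1 or E18.5 female replicate 2. With at least 1000 genes per cell 2 passed, with a mitochondrial limit of 5% 1 passed, and with clusters at resolution 2 3 passed.

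No class passed between males and females. Blood endothelium had the lowest p, 0.120 unadjusted (male share 1.34 ± 0.41%, female 1.10 ± 0.18%, n = 6 each; difference 0.235 points; adjusted p = 0.467). Mesenchyme was at 81.2 ± 5.90% in males and 85.1 ± 3.47% in females (-3.91 points, adjusted p = 0.467), and erythroid cells at 5.07 ± 5.98% and 2.23 ± 1.85% (2.84 points, adjusted p = 0.467). Much of both differences came with E14.5 male replicate 2: without it they were -1.71 and 0.725 points. The exact two-sided permutation test of sex within stage had 216 arrangements and a smallest possible p of 0.00926. It called 0 of 9 classes, 0 of them at an unadjusted p of 0.05.

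**Figure D1:**
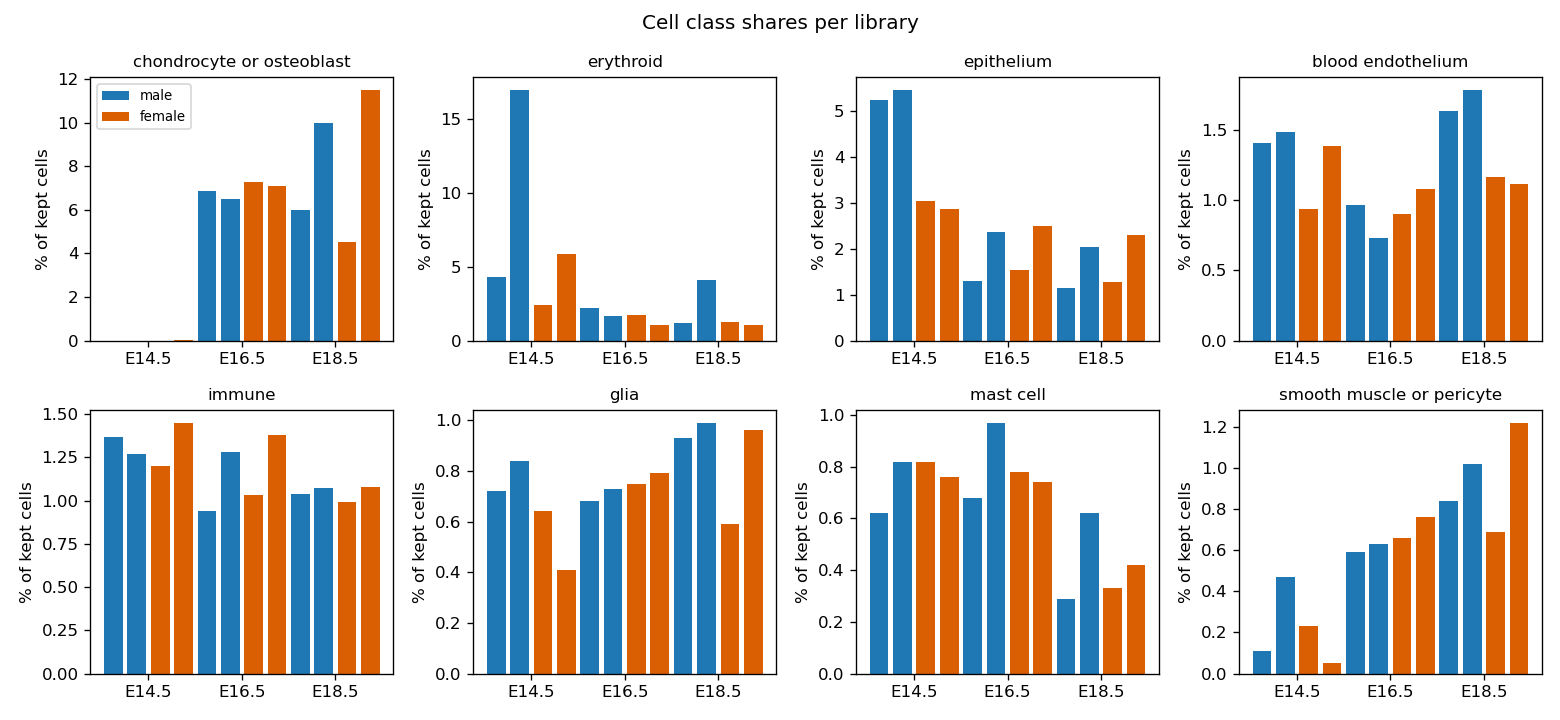
Share of kept cells of each class other than mesenchyme in each of the 12 libraries. Chondrocyte-or-osteoblast-like cells go from 0.00% at E14.5 to 6.92% at E16.5 and 8.01% at E18.5, while epithelium goes from 4.16% to 1.69%.

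Which mesenchymal genes differ between the sexes across the 3 stages? Metallothionein genes, Smoc1 and Fkbp5 were higher in males, and the estrogen and progesterone receptor genes were higher in females. The metallothioneins Mt2 (ENSMUSG00000031762.7, chromosome 8, 94172664 to 94173568; 2.58 ± 0.22, adjusted p = 0.000333) and Mt1 (ENSMUSG00000031765.8, chromosome 8, 94179082 to 94180327; 2.34 ± 0.19, adjusted p = 0.000366) had the largest male excess among the genes that the naming rule admits (n = 6 male and 6 female libraries; positions here and below are on GRCm38/mm10, GENCODE M21, counted from 1). At E18.5 Mt2 stood at 79.0 ± 12.2 CPM in males and 5.46 ± 1.26 in females, and Mt1 at 345 ± 71.5 and 30.4 ± 5.79. Smoc1 (ENSMUSG00000021136.13, chromosome 12, 81026808 to 81186414), which codes for a secreted modulator of bone morphogenetic proteins, rose by 2.25 ± 0.15, adjusted p = 4.78e-05. Fkbp5 (ENSMUSG00000024222.16, chromosome 17, 28399094 to 28517527), a co-chaperone of steroid receptors, rose as well (log2 fold change 1.21 ± 0.05, adjusted p = 6.64e-08), from 26.6 ± 1.56 against 14.3 ± 1.36 CPM at E14.5 to 56.3 ± 2.82 against 22.2 ± 0.394 CPM at E18.5. The contractile genes Acta2 (1.26 ± 0.27, adjusted p = 0.0237) and Des (1.03 ± 0.16, adjusted p = 0.00411) were higher in males too, as were Tpd52l1 (ENSMUSG00000000296.8, chromosome 10, 31332376 to 31445958; 1.23 ± 0.07, adjusted p = 1.48e-06), the peptide hormone gene Nts (1.05 ± 0.13, adjusted p = 0.00066), Klhl2 (0.98 ± 0.11, adjusted p = 0.000398) and Usp51 (0.98 ± 0.09, adjusted p = 8.55e-05).

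The estrogen receptor gene Esr1 (ENSMUSG00000019768.16, chromosome 10, 4611593 to 5005614) had the largest male deficit among the genes that the naming rule takes for the size of their change (log2 fold change -1.12 ± 0.11, adjusted p = 0.000184). Gdf5, given below as a list member, was lower still. The progesterone receptor gene Pgr (ENSMUSG00000031870.16, chromosome 9, 8899833 to 8968611; -0.87 ± 0.15, adjusted p = 0.00329) was lower in males as well. Other genes that were lower in males were Syt1 (-0.98 ± 0.08, adjusted p = 2.53e-05), Itga4 (-0.90 ± 0.21, adjusted p = 0.0295), Col8a1 (-0.90 ± 0.12, adjusted p = 0.00216), the transcription factor Foxp2 (-0.86 ± 0.05, adjusted p = 3.77e-06), the water channel gene Aqp1 (-0.83 ± 0.07, adjusted p = 3.86e-05), Nefm (-0.83 ± 0.23, adjusted p = 0.049), Ldb2 (-0.80 ± 0.06, adjusted p = 1.54e-05), Pde10a (-0.77 ± 0.07, adjusted p = 6.56e-05) and Gfra1 (-0.76 ± 0.09, adjusted p = 0.0007). Srd5a2 (ENSMUSG00000038541.7, chromosome 17, 74016955 to 74047916), whose enzyme turns testosterone into dihydrotestosterone, rose in males (0.81 ± 0.14, adjusted p = 0.00353). Runx1 (0.01 ± 0.11, adjusted p = 0.977) and Hoxd13 (0.08 ± 0.04, adjusted p = 0.283) did not pass. edgeR called 2701 of 16644 genes, 1786 higher and 915 lower in males, with 5062 at an unadjusted p of 0.05; 159 moved at least 2-fold, 100 up and 59 down. Of the 2701 genes 104 lie on the X chromosome and 1 on the Y. Without TMM scaling the counts were 1443 higher and 1094 lower. Leaving out E14.5 female replicate 1 gave 1723 genes, E16.5 male replicate 2 1662, E16.5 female replicate 1 1690 and E16.5 female replicate 2 1722.

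Averaged over the stages, cell cycle genes were higher in males. Of 49 G2M phase genes 46 rose, 0 fell and 3 did not pass (median 0.44; camera adjusted p = 2.46e-36, and adjusted p = 0.247 with an estimated correlation), with Cdca3 at 0.56 ± 0.04. Of 29 S phase genes 26 rose, 0 fell and 3 did not pass (median 0.37; adjusted p = 3.33e-19, and adjusted p = 0.247 with an estimated correlation), with Chaf1b at 0.68 ± 0.06. Stage by stage, the G2M genes that rose were 0 at E14.5 (median -0.04), 0 at E16.5 (median -0.05) and 48 at E18.5 (median 1.42), and the S phase genes 0, 0 and 28. Smooth muscle contraction genes rose in 8 of 18 cases and fell in 0 (Tagln 0.60 ± 0.07, Myl9 0.36 ± 0.06; adjusted p = 0.00284, and adjusted p = 0.247 with an estimated correlation). Of 41 androgen response genes 16 rose and 4 fell (adjusted p = 0.0057, and adjusted p = 0.391 with an estimated correlation). Hpgd (1.66 ± 0.12) and the sterol enzyme gene Idi1 (0.69 ± 0.08) were among those that rose, and Arid5b (-0.38 ± 0.04), Elovl5 (-0.28 ± 0.06), Inpp4b (-0.42 ± 0.09) and Tsc22d1 (-0.14 ± 0.04) were those that fell; the last 3 lie outside the naming rule and are named after their values were seen.

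The other lists did not pass camera in this comparison, although members of them did. Among steroid receptors and enzymes 2 rose and 7 fell of 16 (adjusted p = 0.156; Hsd17b12 0.30 ± 0.04, Nr3c2 -0.64 ± 0.10). Extracellular matrix genes rose in 7 of 33 cases (adjusted p = 0.162; Col12a1 0.38 ± 0.09, Col6a3 0.25 ± 0.06), and cartilage and bone genes in 6 of 20, with 1 lower, the joint growth factor gene Gdf5 (adjusted p = 0.156; Gdf5 -1.71 ± 0.32, Col9a1 0.81 ± 0.20). BMP and FGF genes rose in 7 and fell in 1 of 30 cases (Dusp6 0.34 ± 0.05, Fgf2 -0.27 ± 0.06; adjusted p = 0.793 in the downward direction, against a median of 0.01 and a mean of 0.02). Wnt genes split 3 up and 3 down of 34 (Sp5 0.45 ± 0.11, Dkk2 -0.50 ± 0.09; adjusted p = 0.129), and in the hedgehog list 1 of 13 fell, Foxf2 (-0.29 ± 0.07; adjusted p = 0.229). In the list of genital tubercle patterning factors 1 of 31 rose, Eya1 (0.26 ± 0.06; adjusted p = 0.419 downward, against a median of 0.01 and a mean of -0.01). Hypoxia and glycolysis genes rose in 7 and fell in 1 of 24 cases (Gapdh 0.26 ± 0.05; adjusted p = 0.0987). Interferon genes split 1 up and 1 down of 16 (adjusted p = 0.317; Ifitm3 0.28 ± 0.04, Ifi27l2a -0.60 ± 0.17). Of 13 basal keratinocyte genes 1 rose, Igfbp2 (0.81 ± 0.05; adjusted p = 0.841, median -0.06, mean 0.03). Of 14 urethral or endodermal epithelium genes 2 rose and 1 fell (Cldn3 1.43 ± 0.35, Sox21 -1.07 ± 0.26; adjusted p = 0.419). None of the 27 epidermal differentiation genes (median 0.38; adjusted p = 0.353) or the 20 dissociation stress genes passed (median -0.06; adjusted p = 0.187). The sex-linked genes all passed, 4 up and 6 down (camera adjusted p = 0.187 downward, median -0.36, mean 2.17), and the list of reporter driver genes had 1 tested member, too few for camera.

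**Figure D2:**
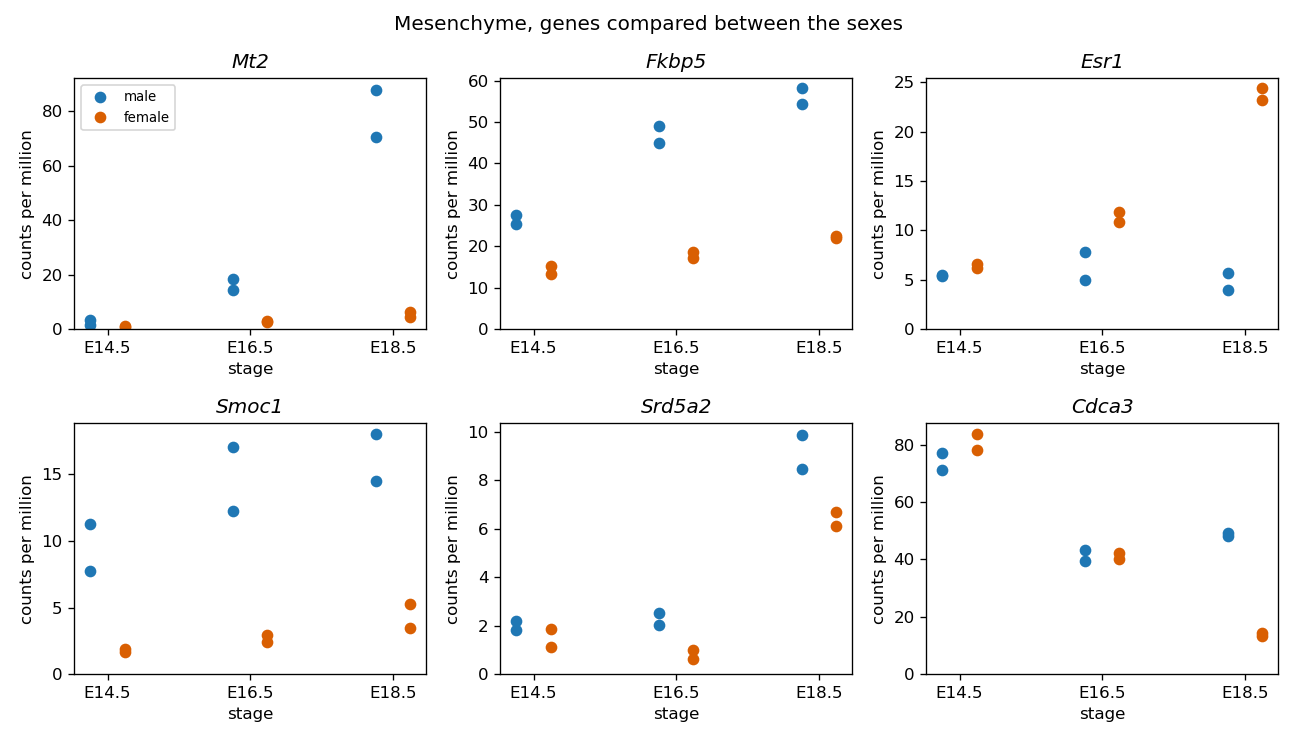
CPM of Mt2, Fkbp5, Esr1, Smoc1, Srd5a2 and Cdca3 in the mesenchyme of each library. Mt2 at E18.5 stands at 79.0 ± 12.2 CPM in males against 5.46 ± 1.26 in females, and Esr1 at 4.86 ± 1.22 against 23.8 ± 0.863.

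Which sex differences are already there at E14.5? Few genes passed. Fkbp5 (0.90 ± 0.09, adjusted p = 0.000573; n = 2 male and 2 female libraries) and the transcription factor gene Zbtb16 (1.16 ± 0.17, adjusted p = 0.0414) rose in males, as did the endothelin gene Edn3 (0.81 ± 0.12, adjusted p = 0.0192), Smoc1 (2.42 ± 0.27, adjusted p = 0.01), the potassium channel gene Kcnc1 (2.86 ± 0.27, adjusted p = 0.000573), Tusc1 (0.70 ± 0.08, adjusted p = 0.00318) and Cep250 (0.55 ± 0.09, adjusted p = 0.0357). Pbdc1 (-0.59 ± 0.08, adjusted p = 0.01) and Pigt (-0.46 ± 0.06, adjusted p = 0.0111) fell. Of these, Smoc1 and Kcnc1 lie outside the naming rule and were chosen after their values were seen. Of 41 androgen response genes 3 rose and 0 fell (Hpgd 1.47 ± 0.21; camera adjusted p = 2.44e-08, and adjusted p = 0.261 with an estimated correlation). Interferon response genes also passed camera upward (median 0.71; adjusted p = 3.18e-10, and adjusted p = 0.261 with an estimated correlation). No member passed alone (Isg15 2.87 ± 0.62, Ifitm3 0.39 ± 0.08), while 8 were higher when adjusted over the list alone. Matrix genes passed upward too, with no member called (Col12a1 0.57 ± 0.15; median 0.13; adjusted p = 0.0038, and adjusted p = 0.825 with an estimated correlation). Esr1 (-0.23 ± 0.19), Pgr (-0.67 ± 0.25) and Srd5a2 (0.43 ± 0.25) did not pass at this stage. edgeR called 13 genes, 10 higher and 3 lower, of which 1 lies on the X chromosome (lower in males) and 1 on the Y, and 868 at an unadjusted p of 0.05; DESeq2 called 63. Without E14.5 male replicate 1 the count was 66, without E14.5 female replicate 2 it was 5 (Fkbp5 1.00, Kcnc1 2.52, Pigt -0.52, AC116511.4 -0.80 and the Y-linked RP24-540G19.3, 143 and 0 UMIs, ratio at least 25.2, named after their values were seen), and without either E18.5 male library it was 21; with no filter on low counts it was 21.

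At E16.5 Mt2 (2.50 ± 0.35, adjusted p = 0.0244), Smoc1 (2.45 ± 0.27, adjusted p = 0.00386), the relaxin receptor gene Rxfp1 (2.28 ± 0.30, adjusted p = 0.00849) and Mt1 (2.06 ± 0.32, adjusted p = 0.0469) rose in males (n = 2 and 2). Cntn4 (-1.01 ± 0.15, adjusted p = 0.0104), Gabra2 (-0.94 ± 0.15, adjusted p = 0.0156), Aqp1 (-0.93 ± 0.12, adjusted p = 0.00381), Syt1 (-0.91 ± 0.13, adjusted p = 0.00706) and Pcdh17 (-0.83 ± 0.11, adjusted p = 0.00467) fell. Srd5a2 rose (1.48 ± 0.27, adjusted p = 0.0332), while Esr1 (-0.83 ± 0.19) and Pgr (-0.97 ± 0.27) did not pass. Smooth muscle genes rose in 2 of 18 cases (Actg2 2.05 ± 0.36, Tagln 0.63 ± 0.11; adjusted p = 5.07e-06, and adjusted p = 0.15 with an estimated correlation). Of 41 androgen response genes 4 rose and 1 fell, Arid5b (-0.44 ± 0.06; adjusted p = 0.00271, and adjusted p = 0.532 with an estimated correlation). In 7 more lists camera passed with at most 1 member called (BMP and FGF adjusted p = 0.0116, patterning factors 0.00335, S phase 0.00271, epidermal differentiation 7.1e-07, all upward; G2M 0.0239, stress 0.0121, interferon 0.0116, all downward), and each had an adjusted p of 0.532 or more with an estimated correlation. edgeR called 117 genes, 72 higher and 45 lower, of which 7 lie on the X chromosome and 1 on the Y, and 1468 at an unadjusted p of 0.05; DESeq2 called 236. Leaving out E16.5 male replicate 1 gave 41 genes, male replicate 2 23, female replicate 1 29 and female replicate 2 40. Sums over all kept cells gave 54, and sums without the 3 clusters that have a marker of another class among their 10 leading genes 74. Of the 13 genes called at E14.5 8 were called at E16.5, all in the same direction.

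How do the sexes differ at E18.5, the last stage? The plasma protein gene Orm1 (ENSMUSG00000039196.2, chromosome 4, 63344560 to 63348163; 8.64 ± 0.84, adjusted p = 0.000427) and the stem cell antigen gene Ly6a (ENSMUSG00000075602.10, chromosome 15, 74994877 to 74998031; 4.95 ± 0.44, adjusted p = 4.63e-05) had the largest male excess among the genes that the naming rule admits (n = 2 and 2). Orm1 stood at 21.8 ± 8.96 CPM against 0.0511 ± 0.0411, and it has close copies in the genome whose reads a gene count cannot always tell apart. Mt2 (3.85 ± 0.34, adjusted p = 0.000149), the protease inhibitor family gene Wfdc10 (ENSMUSG00000070529.7, chromosome 2, 164656046 to 164657368; 3.79 ± 0.21, adjusted p = 3.83e-07) and Mt1 (3.50 ± 0.34, adjusted p = 0.000319) came next. In the other direction the kinase gene Tec (-2.59 ± 0.46, adjusted p = 0.00537), the hormone gene Stc1 (-2.38 ± 0.28, adjusted p = 0.000698), Esr1 (-2.29 ± 0.20, adjusted p = 2.49e-05), the vasopressin receptor gene Avpr1a (-1.97 ± 0.20, adjusted p = 5.31e-05) and Syt1 (-1.84 ± 0.14, adjusted p = 4.83e-06) were lower in males. Esr1 stood at 4.86 ± 1.22 CPM in males and 23.8 ± 0.863 in females. Pgr was lower as well (-0.98 ± 0.28, adjusted p = 0.0223), and Srd5a2 (0.52 ± 0.22), Runx1 (0.15 ± 0.20) and Hoxd13 (0.18 ± 0.08) did not pass.

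Cell division genes were higher in males at this stage. Of 49 G2M genes 48 rose in males and 0 fell (median 1.42; camera adjusted p = 2.03e-40, and adjusted p = 0.226 with an estimated correlation), among them Cdca3 (ENSMUSG00000023505.13, chromosome 6, 124829547 to 124833701; 1.82 ± 0.08, adjusted p = 8.35e-08), Ube2c (1.83 ± 0.09) and Tpx2 (1.57 ± 0.07). Cdca3 stood at 48.7 ± 0.561 CPM in males and 13.8 ± 0.549 in females. S phase genes rose in 28 of 29 cases (Uhrf1 1.61 ± 0.11, Tyms 1.57 ± 0.10; adjusted p = 1.17e-20, and adjusted p = 0.229 with an estimated correlation). The 4 mesenchyme clusters led by cell cycle genes held 13.2 and 12.3% of mesenchymal cells in the E18.5 male libraries and 3.1 and 3.48% in the female ones, against 8.60 to 9.83% at E16.5 and 16.6 to 19.5% at E14.5. A cluster with Ostn, Wfdc10, Dner and Orm1 among its 10 leading genes held 8.89 and 9.73% of mesenchymal cells in E18.5 males and 0.83 and 1.43% in females. Smooth muscle genes rose in 7 of 18 cases (Tagln 0.99 ± 0.12, Des 1.52 ± 0.27; adjusted p = 0.00428, and adjusted p = 0.229 with an estimated correlation). Hypoxia and glycolysis genes rose in 12 of 24 cases and fell in 1, with Gapdh at 0.82 ± 0.09 and Pkm at 0.82 ± 0.10 (adjusted p = 0.0345, and adjusted p = 0.52 with an estimated correlation). The androgen response list split 13 up and 7 down of 41 (adjusted p = 0.385), with Hpgd at 1.78 ± 0.19 and Arid5b at -0.51 ± 0.06. edgeR called 4859 of 16644 genes, 3109 higher and 1750 lower, and 874 moved at least 2-fold, 497 up and 377 down; 173 of the 4859 lie on the X chromosome and 1 on the Y. This split turns with the scaling: without TMM 1956 were higher and 3488 lower, and the median over all genes went from 0.01 to -0.13. Of the 117 genes called at E16.5 100 were called at E18.5, 98 of them in the same direction. Of the 13 called at E14.5 7 were called at E18.5, 6 of them in the same direction; the other, the X-linked Pbdc1, named after its values were seen, went from -0.59 at E14.5 to 0.24 at E18.5.

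**Figure D3:**
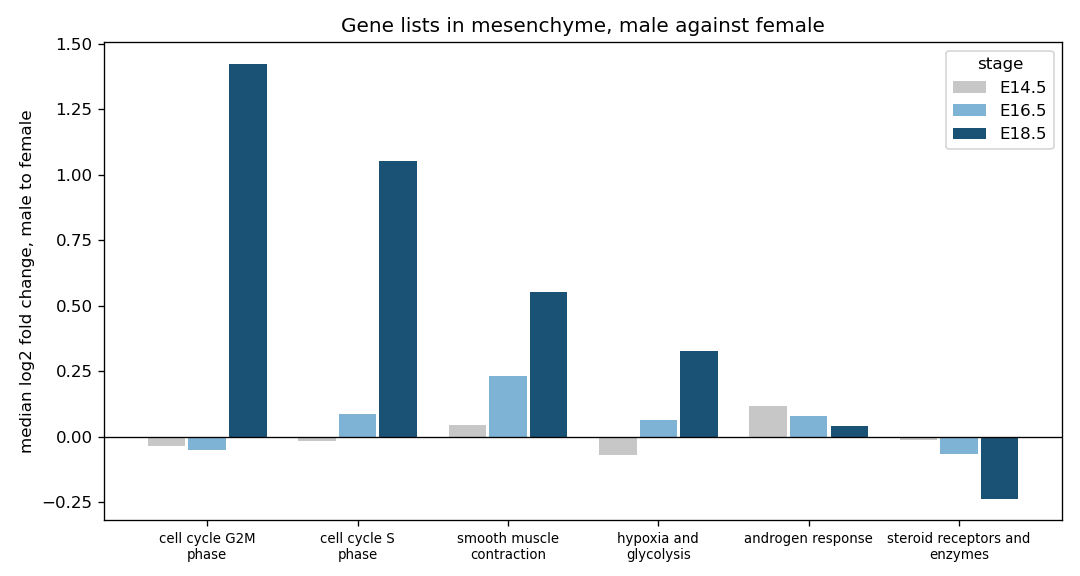
Median log2 male to female fold change of 6 gene lists in mesenchyme at each stage. G2M genes stand at -0.04 at E14.5, -0.05 at E16.5 and 1.42 at E18.5.

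Does the sex difference itself change between E14.5 and E18.5? The male excess grew for Ly6a (4.52 ± 0.82, adjusted p = 0.00576), the Notch-pathway receptor gene Dner (3.07 ± 0.18, adjusted p = 5.28e-06), Wfdc10 (2.70 ± 0.38, adjusted p = 0.000827), Tpd52l1 (2.57 ± 0.16, adjusted p = 5.77e-06) and Mt2 (2.46 ± 0.57, adjusted p = 0.0252), with n = 2 libraries in each of 4 groups. It moved towards females for Neto1 (-2.79 ± 0.39, adjusted p = 0.00131), Tec (-2.70 ± 0.59, adjusted p = 0.0224), Stc1 (-2.41 ± 0.39, adjusted p = 0.00623) and Spon1 (-2.06 ± 0.51, adjusted p = 0.0334). Esr1 (-2.06 ± 0.27, adjusted p = 0.000982) fell by this measure, and Pgr (-0.31 ± 0.38), Srd5a2 (0.09 ± 0.34), Runx1 (-0.01 ± 0.28) and Hoxd13 (0.28 ± 0.11) did not pass. G2M genes rose in 48 of 49 cases (median 1.45; Cdca3 1.95 ± 0.10; adjusted p = 2.55e-47, and adjusted p = 0.183 with an estimated correlation) and S phase genes in 28 of 29 (adjusted p = 5.29e-23, and adjusted p = 0.264 with an estimated correlation). Glycolysis genes rose in 9 of 24 cases (Gapdh 0.93 ± 0.13; adjusted p = 0.0168, and adjusted p = 0.517 with an estimated correlation) and smooth muscle genes in 3 of 18 (Tpm2 0.88 ± 0.14; adjusted p = 0.0389, and adjusted p = 0.44 with an estimated correlation). Interferon genes fell in 3 of 16 cases (Isg15 -2.91 ± 0.80; adjusted p = 0.0168, and adjusted p = 0.578 with an estimated correlation), and Wnt genes fell in 4 and rose in 1 of 34 (Wnt5a -0.63 ± 0.15, Dkk1 0.71 ± 0.12; adjusted p = 0.0452, adjusted p = 0.051 with the replicate number as a block, and adjusted p = 0.44 with an estimated correlation). The edgeR interaction test called 2669 genes, 1951 higher and 718 lower; without TMM the split turned to 1026 higher and 2202 lower, and the median over all genes went to -0.19. Without E14.5 female replicate 2 the count was 1104, and without E18.5 female replicate 2 it was 1745.

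What changes in mesenchyme between E14.5 and E18.5, over both sexes? The clusters that make up the mesenchyme differ by stage. Cluster 5 held 15.7 to 16.9% of mesenchymal cells in the E14.5 libraries and 0 to 0.01% at E18.5. Cluster 4 held 0% at E14.5 and 11.3 to 17.9% at E18.5, and cluster 8 held 0% and 7.53 to 16.3%. The stage comparisons sum over all mesenchyme clusters. The chemokine genes Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889; 7.80 ± 0.43, adjusted p = 2.34e-06), Cxcl2 (7.67 ± 0.56, adjusted p = 1.39e-05), Ccl7 (6.91 ± 0.37, adjusted p = 1.37e-06), Cxcl1 (6.84 ± 0.24, adjusted p = 1.3e-07) and Ccl2 (6.44 ± 0.68, adjusted p = 0.000161) rose (n = 4 and 4 libraries), and Cxcl10 reached 39.1 ± 7.05 CPM in males and 37.7 ± 1.15 in females. In immune cells of the same E18.5 libraries Cxcl10 stood at 275 ± 50.9 CPM (mean ± SD, n = 4). The secreted peptide gene Ostn (6.65 ± 0.20, adjusted p = 1.1e-09), the matrix gene Coch (5.87 ± 0.18, adjusted p = 1.2e-08) and Pi15 (5.73 ± 0.36, adjusted p = 1.37e-06) rose as well. S100a9 (10.66 ± 3.35, adjusted p = 0.0343) had 3 UMIs at E14.5 and 2484 at E18.5 (ratio of CPM 1102.7, 95% counting interval 376.9 to 5351), and its 4 E18.5 libraries ranged from 0.24 to 27.8 CPM. Orm1 (7.88 ± 2.06, adjusted p = 0.0118) had 1 and 2266 UMIs (ratio 3017.9, interval 541.1 to 119253.1), and at E18.5 it stood at 21.8 ± 8.96 CPM in males and 0.0511 ± 0.0411 in females. It did not pass without E18.5 female replicate 1 (7.30). Fxyd7 (-4.89 ± 0.44, adjusted p = 3.5e-05), Cbln2 (-3.06 ± 0.45, adjusted p = 0.000699), Plac8 (-2.98 ± 0.54, adjusted p = 0.00206) and the growth-linked chromatin gene Hmga2 (ENSMUSG00000056758.14, chromosome 10, 120361275 to 120476469; -2.83 ± 0.10, adjusted p = 1.18e-08) fell, with Hmga2 going from 262 ± 0.0579 CPM in E14.5 males to 38.2 ± 5.94 at E18.5. Rprm (-2.77 ± 0.26, adjusted p = 4.25e-05), Lix1 (-2.63 ± 0.10, adjusted p = 2.27e-08), Uchl1 (-2.60 ± 0.16, adjusted p = 1.19e-06), Hs3st4 (-2.47 ± 0.29, adjusted p = 0.000126), the noncoding Rmst (-2.33 ± 0.27, adjusted p = 9.25e-05) and the neuronal tubulin gene Tubb3 (-2.26 ± 0.12, adjusted p = 3.22e-08) fell too. Each of 3 mesenchyme clusters (13497 cells) has a marker of another class among its 10 leading genes, Uchl1 in cluster 5.

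Srd5a2 (2.15 ± 0.17, adjusted p = 8.13e-07), Esr1 (0.87 ± 0.14, adjusted p = 0.000245) and Runx1 (ENSMUSG00000022952.16, chromosome 16, 92601466 to 92826149; 0.75 ± 0.14, adjusted p = 0.00134) rose, and Pgr (-0.56 ± 0.19, adjusted p = 0.0206) and Hoxd13 (-0.14 ± 0.06, adjusted p = 0.0376) fell. For Esr1 this average joins sexes that moved apart: it went from 5.44 ± 0.0124 to 4.86 ± 1.22 CPM in males and from 6.39 ± 0.295 to 23.8 ± 0.863 in females. Matrix genes rose in 30 of 33 cases (Postn 2.45 ± 0.10, Col6a3 1.46 ± 0.07; median 1.04; camera adjusted p = 9.47e-11) and stress genes in 19 of 20 (Nr4a1 3.17 ± 0.10, Zfp36 3.35 ± 0.12; median 1.38; adjusted p = 2.39e-08). Signs of cell quality moved over the same stages: the median mitochondrial share of kept cells was 4.44 to 4.68% in the E14.5 libraries and 5.07 to 6.05% at E18.5, and 355 to 516 and 505 to 981 barcodes per library were over the mitochondrial limit. The E16.5 libraries, in between, had 4.6 to 4.89% and 205 to 389 barcodes. Of 30 BMP and FGF genes 21 rose and 3 fell (Fgf2 1.94 ± 0.07, Chrd 1.33 ± 0.09; adjusted p = 0.000558), and of 41 androgen response genes 25 rose and 7 fell (Zbtb10 1.40 ± 0.08, Ell2 2.06 ± 0.12; adjusted p = 0.00208). G2M genes fell in 48 of 49 cases (median -1.18; adjusted p = 4.86e-20) and S phase genes in 29 of 29 (adjusted p = 8.11e-10). All 6 lists had an adjusted p of 0.356 with an estimated correlation. The cell cycle averages join sexes that changed by different amounts. Clusters led by cell cycle genes went from 16.61 and 18.47% of mesenchymal cells at E14.5 to 13.19 and 12.28% at E18.5 in males. In females they went from 16.89 and 19.47% to 3.1 and 3.48%. Patterning factors did not pass camera (adjusted p = 0.0875), with 5 higher and 15 lower of 31 (Hoxd12 -1.39 ± 0.07), and neither did Wnt genes, 12 higher and 13 lower (Wif1 1.40 ± 0.07, Dkk1 -1.60 ± 0.06; adjusted p = 0.793). In smooth muscle genes 10 rose and 3 fell of 18 (Tagln 1.31 ± 0.08, Synpo2 -0.96 ± 0.09; adjusted p = 0.0758), and in hedgehog genes 6 rose and 2 fell (Hhip 1.98 ± 0.09; adjusted p = 0.319 upward, median -0.05, mean 0.30). edgeR called 11268 of 16644 genes, 5523 higher and 5745 lower, and 2910 moved at least 2-fold. Tested within males and within females as contrasts of the same fit of 6 groups, 8336 and 10062 genes passed. In both 6572 passed, 6382 of them in the same direction. The 2 contrasts share 1 estimate of the spread.

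**Figure D4:**
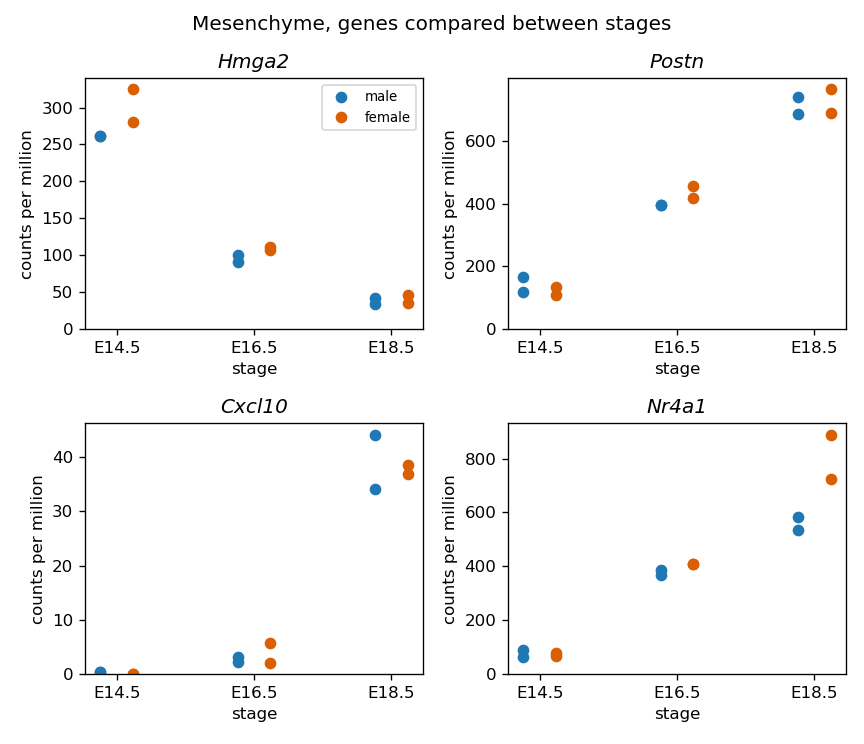
CPM in mesenchyme of Hmga2, Postn, Cxcl10 and Nr4a1 in each library across the 3 stages. Hmga2 falls from 303 ± 31.0 to 41.0 ± 7.88 CPM in females while Postn rises from 122 ± 16.7 to 727 ± 55.8.

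Which part of this is seen between E14.5 and E16.5? Matrix genes rose in 28 of 33 cases (adjusted p = 3.25e-10), BMP and FGF genes in 19 of 30, with 2 lower (4.9e-05), androgen response genes in 23 of 41, with 5 lower (0.000881), stress genes in 15 of 20, with 1 lower (1.33e-05), and smooth muscle genes in 11 of 18, with 1 lower (0.0091). G2M genes fell in 48 of 49 cases (1.15e-21) and S phase genes in 28 of 29 (2.1e-10). Epidermal genes rose in 22 of 27 cases within mesenchyme, with 1 lower (1.33e-05; median 4.28, or 4.16 with the 6 members at 0 at E14.5 set to their bound), and these are markers of another cell class. With an estimated correlation the adjusted p of these lists was 0.294 or more. Esr1 (0.53 ± 0.14, adjusted p = 0.00688) and Runx1 (0.37 ± 0.14, adjusted p = 0.0486) rose, Pgr fell (-0.53 ± 0.18, adjusted p = 0.0285), and Srd5a2 (-0.34 ± 0.18) did not pass. edgeR called 9556 genes, 4749 higher and 4807 lower (n = 4 and 4 libraries).

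And between E16.5 and E18.5? With the same E16.5 libraries as in the comparison before, Srd5a2 rose (2.50 ± 0.18, adjusted p = 5.3e-06), while Esr1 (0.34 ± 0.14), Pgr (-0.03 ± 0.20) and Runx1 (0.38 ± 0.14) did not pass. Matrix genes rose in 18 of 33 cases (adjusted p = 5.16e-08), stress genes in 12 of 20 (2.02e-08) and hypoxia genes in 10 of 24 (0.000235). G2M genes fell in 43 and rose in 2 of 49 cases (4.2e-17), S phase genes fell in 14 of 29, with 1 higher (0.000408), patterning factors in 11 of 31, with 3 higher (0.00918), and epidermal genes in 14 of 27, with 1 higher (0.000408; median -1.64). With an estimated correlation the adjusted p was 0.449 or more. The cell cycle averages join sexes that moved apart: the clusters led by cell cycle genes went from 9.83 and 8.93% of mesenchymal cells at E16.5 to 13.2 and 12.3% at E18.5 in males, and from 8.81 and 8.60% to 3.1 and 3.48% in females. edgeR called 5739 genes, 2757 higher and 2982 lower; without TMM 1968 were higher and 4647 lower (n = 4 and 4 libraries).

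Do epithelial cells differ between the sexes? Over all stages no epithelial gene passed in edgeR outside the sex-linked list. Within single stages edgeR called 1 gene at E14.5 (Blvrb, 2.24), 0 at E16.5 and 3 at E18.5 (Aldh1a3 2.63, Fabp4 -4.16 and Krt35, 0 and 129 UMIs, ratio at most 0.0367), named after their values were seen. Blvrb is known from red cells; Hemgn, another such gene, stood at 71.0 ± 36.1 CPM in E14.5 male epithelium and 8.09 ± 10.3 in female without being called. The signalling gene Shh, made by urethral epithelium, had a log2 fold change of -1.26 ± 0.31, adjusted p = 0.903 (n = 6 and 6), and Shh had 3 to 16 epithelial UMIs in each male and 8 to 46 in each female library. Runx1 (-0.26 ± 0.19) and Hoxd13 (0.26 ± 0.32) did not pass either. The hedgehog receptor gene Ptch1 was at -0.52 ± 0.30 and the target gene Gli1 at -0.73 ± 0.30, also without passing. Of 10047 genes tested in both classes, 9 had a sex difference that differed between epithelium and mesenchyme (limma, 800 at an unadjusted p of 0.05). No list passed: the androgen response list had a median of -0.04 (adjusted p = 0.634) and the urethral list one of -0.13 (adjusted p = 0.634), of which 3 genes were lower in males when adjusted over the list alone. edgeR called 0 of 10177 genes and 321 at an unadjusted p of 0.05. DESeq2 called 1, Gm47283 (log2 fold change -1.01), named after its value was seen. With no filter on low counts edgeR called 74, with a mitochondrial limit of 5% 1 (Dapl1, -1.28), and over all kept cells 2544. Without E16.5 male replicate 2 it called 8, without E14.5 male replicate 2 2 (Blvrb 0.93 and RP23-79J21.3 -3.28), and 1 each without E14.5 female replicate 2 (Fabp4 -1.87), E16.5 male replicate 1 (Calml3 -1.48), E18.5 male replicate 2 (Prrx2 1.65) and E18.5 female replicate 2 (Gm47283 -1.15). These too are named after their values were seen.

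How does the epithelium change from E14.5 to E18.5? The sebaceous keratin gene Krt79 (6.73 ± 0.84, adjusted p = 0.00293), Cxcl1 (5.39 ± 0.45, adjusted p = 3.99e-05), Calm4 (4.78 ± 0.97, adjusted p = 0.0251) and the immediate early genes Egr3 (4.76 ± 0.37, adjusted p = 5.51e-05) and Arc (4.42 ± 0.69, adjusted p = 0.00606) rose (n = 4 and 4). Psca (9.36 ± 2.33, adjusted p = 0.0488) also passed, but with 1 library left out it passed in 1 of 12 runs, and E18.5 female replicate 2 stood at 2.06 CPM against 769 to 2488 in the other E18.5 libraries and 0.763 to 3.82 at E14.5. Without E18.5 female replicate 1 its log2 fold change was 4.75. So did 3 genes with few counts at E14.5: Ly6a (6.51 ± 1.33, adjusted p = 0.0221; 2 and 149 UMIs, ratio 84.3, 95% counting interval 22.9 to 702.5), Grin2b (5.98 ± 0.72, adjusted p = 0.000368; 1 and 100 UMIs, ratio 113.2, interval 19.8 to 4513.5) and Abi3bp (5.00 ± 0.65, adjusted p = 0.000457; 3 and 95 UMIs, ratio 35.8, interval 11.9 to 176.8). Genes known from red cells were among those that fell: Slc4a1 (-6.79 ± 1.26, adjusted p = 0.0277; 265 and 1 UMIs, ratio 0.00427, interval 0.000108 to 0.024), Hemgn (-6.68 ± 1.12, adjusted p = 0.0096; 387 and 3, ratio 0.00877, interval 0.0018 to 0.0258), Ermap (121 and 0, ratio at most 0.035; adjusted p = 0.0312), Rhd (-6.07 ± 1.12, adjusted p = 0.0207; 276 and 2, ratio 0.0082, interval 0.000988 to 0.0299), Icam4 (-4.70 ± 1.28, adjusted p = 0.0485; 171 and 3, ratio 0.0199, interval 0.00405 to 0.059) and Klf1 (-3.81 ± 0.99, adjusted p = 0.0207; 127 and 2, ratio 0.0178, interval 0.00213 to 0.0657). Much of the E14.5 signal of these genes lay in the male libraries: Hemgn stood at 71.0 ± 36.1 CPM in males and 8.09 ± 10.3 in females, and Ermap at 23.1 ± 14.7 and 0.885 ± 1.25. Car2 (-4.86 ± 0.81, adjusted p = 0.0134) fell with the same pattern over the E14.5 libraries as Hemgn. It stood at 291.8 and 137.2 CPM in the male libraries and at 2.516 and 23.6 in the female ones. Its fall may therefore belong with that of the red cell genes, which was not tested. Other genes that fell were Fam19a4 (-4.26 ± 0.75, adjusted p = 0.00288) and Ube2l6 (-4.00 ± 0.74, adjusted p = 0.00393). Erythroid cells held 10.65 ± 8.96% of cells in E14.5 males and 4.15 ± 2.41% in E14.5 females, and 1.89 ± 1.47% at E18.5.

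Of 13 basal keratinocyte genes 6 rose and 1 fell (Lamb3 1.42 ± 0.17, Itgb4 0.97 ± 0.14; camera adjusted p = 0.000187), and of 15 urethral genes 2 rose and 2 fell, Krt8 (-2.25 ± 0.53, but 1.85 over all kept cells) and Krt18 (-1.39 ± 0.29), without passing camera (adjusted p = 0.981). Matrix genes rose in 14 of 29 cases (Fn1 1.36 ± 0.18, Col3a1 2.34 ± 0.25; adjusted p = 4.16e-11), stress genes in 11 of 20 (Hspa1b 2.34 ± 0.22; adjusted p = 2.96e-14) and androgen response genes in 13 of 33 (Sgk1 4.04 ± 0.44; adjusted p = 9.88e-07). Hedgehog genes rose in 2 of 11 cases (Boc 1.73 ± 0.27; adjusted p = 0.00399), BMP and FGF genes in 5 of 19 (Fgfr1 1.55 ± 0.15; adjusted p = 0.00736) and epidermal genes in 1 of 27 (Lgals7 2.27 ± 0.48; median 2.23, or 2.10 with members at 0 set to their bound; adjusted p = 0.0196). G2M genes fell in 20 of 49 cases (Birc5 -1.11 ± 0.16; adjusted p = 2.18e-14) and S phase genes in 5 of 29 (adjusted p = 7.85e-05). None of the 9 lists passed with an estimated correlation (adjusted p of 0.204 or more). The matrix genes also rose in mesenchyme, which holds most of the kept cells. RNA of that class may be part of the epithelial matrix counts, and its share was not measured. At E18.5 Col3a1 was highest in male replicate 1 (288 CPM against 107.6 to 189.1), while Fn1 was lowest there (62.3 against 79.3 to 101.5). Runx1 (0.11 ± 0.24), Shh (0.51 ± 0.40) and Hoxd13 (-0.03 ± 0.37) did not pass. edgeR called 1366 of 10177 genes, 759 higher and 607 lower, and without TMM 661 higher and 875 lower. Leaving out E14.5 male replicate 1 gave 662 genes, E18.5 male replicate 1 808 and E18.5 male replicate 2 895, and a mitochondrial limit of 5% gave 174, no filter on low counts 2133 and all kept cells 11439.

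Does blood endothelium differ between the sexes? The sterol enzyme genes Idi1 (0.80 ± 0.12, adjusted p = 0.000275), Msmo1 (0.75 ± 0.11, adjusted p = 0.000432), Cyp51 (0.97 ± 0.15, adjusted p = 0.00128), Fdps (0.51 ± 0.10, adjusted p = 0.0175) and Acat2 (0.61 ± 0.14, adjusted p = 0.0472) rose (n = 6 and 6). The lipid carrier gene Apoe (-0.87 ± 0.10, adjusted p = 3.4e-06), the cholesterol exporter gene Abca1 (-0.38 ± 0.08, adjusted p = 0.0308) and the lipoprotein receptor gene Scarb1 (-0.45 ± 0.07, adjusted p = 0.00061) fell. Sostdc1 (2.11 ± 0.40, adjusted p = 0.0104) rose and Asb4 (-0.52 ± 0.08, adjusted p = 0.000377) fell. These genes were named after their values were seen, since the naming rule written before the data covers mesenchyme and epithelium only. Sostdc1 was also among the erythroid calls between the sexes at E18.5. RNA of another class may be part of the endothelial counts, and its share was not measured. edgeR called 32 of 10862 genes, 17 higher and 15 lower, of which 1 lies on the X chromosome and 1 on the Y, and 976 at an unadjusted p of 0.05; DESeq2 called 16. Without E14.5 male replicate 2 the count was 111. It was 20 without E14.5 male replicate 1 or E14.5 female replicate 1, 21 without E14.5 female replicate 2, 16 without E16.5 male replicate 1, 17 without E16.5 male replicate 2, 13 without E16.5 female replicate 1, 19 without E16.5 female replicate 2, 18 without E18.5 male replicate 2 and 15 without E18.5 female replicate 1. It was 133 with no filter on low counts, 14 with a mitochondrial limit of 5%, 20 without doublet removal and 2544 over all kept cells.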

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

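Of the tests in this part, the clusters made without cell cycle genes, the dissociation test and the immune RNA test were chosen only after results were seen.

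In mesenchyme 2669 genes had a sex difference that itself differed between E18.5 and E14.5 in the edgeR interaction test. The male to female difference grew for Ly6a (4.52), Dner (3.07), Wfdc10 (2.70), Tpd52l1 (2.57) and Mt2 (2.46). It moved towards females for Neto1 (-2.79), Tec (-2.70), Stc1 (-2.41), Spon1 (-2.06) and Esr1 (-2.06). A signal was also present in genes that no comparison uses: the reporter eGFP had at least 244 UMIs in each library and tdTomato at least 3357.

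The E18.5 sex difference in mesenchyme, with cell cycle genes higher in males, was weighed first. Sequencing depth is not decided: the G2M median was 1.41 after thinning (1.42 before), but thinning keeps the expected ratio of well-counted genes. A general delay of male embryos is not decided either. The median shift towards E16.5 in blood endothelium (0.038), glia (-0.058) and immune cells (0.069) was 0.09 of that in mesenchyme (0.446). Epithelium, outside this test, stood at -0.205. These classes hold far fewer cells than mesenchyme and were not matched to it, and counting noise pulls such a shift towards 0. The mix of the original mesenchyme clusters did not account for the whole difference over the called genes. With an equal mix they kept a slope of 0.71 (0.67 to 0.72 over 4 pairings). For the G2M genes the part of the mix is not decided. With clusters made without cell cycle genes the G2M median was 0.79, against 1.23 over all mesenchyme. This used the 17 of 27 clusters that have at least 20 cells in each E18.5 library (88.4 and 80.5% of mesenchyme cells in males, 65.2 and 61.5% in females). The others include clusters nearly confined to 1 sex, such as 1 with 0.24 and 0.12% of male and 9.9 and 8.5% of female cells. Clusters made in this way can also hold dividing and resting cells together. With the original clusters, which are built partly from the cell cycle genes, an equal mix took the median of the called G2M genes to -0.113. Without the clusters led by cell cycle genes the G2M median was 0.901, against 1.423 with them. Part of the difference may therefore be a larger share of dividing cells. A sex difference in proliferation stays open, untested, and so does the part of the clusters left out.

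The lack of epithelial calls between the sexes over all stages was weighed second. The tables argue against size alone, since mesenchyme drawn down to the epithelial number of cells, with about as many UMIs in 5 libraries and fewer in 7, still gave 176 genes (95 to 320 over 10 draws). A larger spread between epithelial libraries is a candidate explanation, since the biological coefficient of variation was 2.06 times that of these draws (1.98 to 2.24), which are matched in cells but not in UMIs throughout. A smaller sex difference in epithelium also stays open: called mesenchymal genes had a slope of 0.07 in epithelium.

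Stress and chemokine genes higher in mesenchyme at E18.5 were weighed last. A response to dissociation may contribute, since the stress list rose from E14.5 to E18.5 with a median of at least 0.61 in each of 7 classes. RNA of mesenchyme, which holds most of the kept cells, may be part of the counts of the other classes. Its share was not measured, so the 7 classes may not be separate evidence. The median mitochondrial share of kept cells was 4.44 to 4.68% at E14.5, 4.6 to 4.89% at E16.5 and 5.07 to 6.05% at E18.5. Between E14.5 and E16.5 the stress median was 0.76 in mesenchyme, and over the classes it ran from -0.06 (glia) to 1.99 (epithelium). Stage and handling cannot be separated by this design. The tables argue against free RNA of immune cells as the whole cause, since each of 5 chemokine genes was at least 7.4 times above what the median immune marker gives in each of 4 libraries; that test assumes that all immune transcripts leak alike. An earlier test, whether chemokines are higher in mesenchyme than in immune cells, held for 0 of 5 and decided nothing. A change with stage stays open, untested.

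Other splits of the same libraries tested whether chance gives as many genes. In an additive model the sex split called 227 genes in mesenchyme (2701 in the fit of 6 groups), and 1 of 40 splits, the real one, reached that; the highest other gave 10. In blood endothelium it called 16, reached by 1 of 40, and the highest other gave 3. In epithelium it called 0, which any split reaches (40 of 40), so this test says nothing about epithelial sex; the highest other gave 24. The stage splits called 9647 genes (E18.5 against E14.5), 9745 (E16.5 against E14.5) and 4096 (E18.5 against E16.5) in mesenchyme and 1743 in epithelium, each reached by 1 of 34, with 0, 0, 20 and 1 in the highest other. Apart from epithelial sex, where the test cannot decide, no other fitted split called as many genes as the real one. Only part of the possible sex splits were fitted. The models of the other splits also leave out the real grouping, which adds to their residual spread. Chance is therefore not excluded, and differences of litter or handling were not tested.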

How the results depend on the processing

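The tests without mesenchyme clusters that have a marker of another class among their 10 leading genes, with chondrocyte-or-osteoblast-like cells and without cell cycle clusters were chosen only after results were seen.

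Of 277 counts of called genes under an alternative, 227 stayed within 1.5 times the reported count, and the 3 mesenchyme stage counts and the E18.5 sex count did so in every setting. Of 315 class share values 261 kept their direction and side of the threshold. With no filter on low counts the genes called were 21 (mesenchyme sex at E14.5), 74 (epithelium sex), 2133 (epithelium stage) and 133 (endothelium sex). With DESeq2 they were 63 (E14.5 sex), 236 (E16.5 sex), 1 (epithelium sex) and 16 (endothelium sex). Sums over all kept cells mix the classes and gave 54 (E16.5 sex), 2544 (epithelium sex and endothelium sex alike) and 11439 (epithelium stage). With at most 5% mitochondrial UMIs there were 1 (epithelium sex), 174 (epithelium stage) and 14 (endothelium sex), and without doublet removal 20 (endothelium sex). Without clusters that have a marker of another class among their leading genes E16.5 sex gave 74.

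Leaving out 1 library gave 1662 (without E16.5 male replicate 2) to 3158 (without E14.5 male replicate 2) genes for mesenchyme sex, 5 to 66 at E14.5, 23 to 156 at E16.5, 3244 to 5230 at E18.5 and 1104 to 3447 for the interaction. It gave 0 to 8 for epithelium sex, 662 to 1861 for epithelium stage and 13 to 111 for endothelium sex. The lone library left in a group is assumed to vary like the other groups.

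With an estimated correlation camera called 0 lists in each of the 9 comparisons in which the preset correlation called any. Fry, which tests whether a list moves on balance one way without reference to other genes, called 15 (E18.5 against E14.5), 4 (E18.5 against E16.5), 7 (sex over all stages), 0 (E14.5 sex), 2 (E16.5 sex) and 8 (E18.5 sex) in mesenchyme. For E18.5 sex the fry values and the estimated correlations also depend on rounding: a run of the same code with other processor settings of the matrix library gave slightly different values and 1 list fewer with fry, the sex-linked one. The values here are those of the fixed settings in the run script. Classes called across stages were 2 with at least 1000 genes per cell, 1 with at most 5% mitochondrial UMIs, 3 at Leiden resolution 2 and 3 to 6 leaving out a library. The mesenchyme share, male minus female, ran from -8.524 (at most 5% mitochondrial UMIs) to -1.71 points (without E14.5 male replicate 2) and the erythroid share, male minus female, from 0.704 (at least 1000 genes per cell) to 4.951 (without E14.5 male replicate 1), passing in no setting. The immune share reversed to 0.027 points per day with at most 5% mitochondrial UMIs. Log2 stage changes reversed for Col2a1 in mesenchyme (0.34 over all kept cells, 0.39 with chondrocyte-or-osteoblast-like cells) and, over all kept cells, for the epithelial Krt8 (1.85); these settings add the cells of other classes. For the other changes in this part the cause was not tested.

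With the replicate number as a block no count of genes moved by over 1.5 times, while the Wnt list no longer passed camera for the interaction (adjusted p = 0.051) and the patterning factor list passed for E18.5 sex (adjusted p = 0.0473). Of 15 pairs of groups 3 had a correlation over 0.1 between same-numbered replicates (-0.074 to 0.337), and in 3 of 6 groups the libraries matched their own number best. The highest correlation was that of E18.5 males with E18.5 females. The block is a single term shared by all stages, so it does not test a pairing at E18.5 alone. A log2 change of 0.5 was recovered in 12.3% of simulated genes in epithelium and 70.8% in mesenchyme.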

Other observations

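The test of sterol genes was chosen only after the endothelial result was seen.

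A list of 21 genes of sterol metabolism was made after members of it had been called in blood endothelium, so endothelium cannot test it; there 6 of 20 rose and 0 fell. In mesenchyme of the same libraries 18 of 21 rose and 0 fell (median log2 fold change 0.36, 21 of 21 positive; camera p = 4.72e-15, and p = 0.0349 with an estimated correlation), with Msmo1 at 0.72 and Fdps at 0.63. In epithelium 0 of 20 passed in edgeR (median 0.00, 11 of 20 positive; p = 0.973, and p = 0.991 with an estimated correlation). Leaving out 1 library gave 3 to 8 genes in endothelium and 15 to 18 in mesenchyme, and DESeq2 gave 3 and 17.

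The sex comparison was also planned, for counts only, in the other named classes with enough cells in every library. The stage comparison in these classes was not named in that plan. Between the sexes edgeR called 4 genes in glia (Cd59a -1.38, Tenm1 -0.98, Gm47283 -0.95 and Cdc20 0.79, named after their values were seen), 36 in immune cells, 13 in erythroid cells and 0 in mast cells (362 at an unadjusted p of 0.05; DESeq2 was not run there). Between E14.5 and E18.5 it called 1704, 1918, 1900 and 3694. The erythroid calls between the sexes include Igfbp3, Mgp, Nog and Rspo3, and those between stages Postn and Mgp (all named after their values were seen). These genes are known from connective tissue, so RNA of another class may be part of the erythroid counts; its share was not measured. Calls between the sexes outside mesenchyme also include members of the cell cycle lists, named after their values were seen. They are Tpx2 in erythroid cells, Cdk1 in immune cells, Cdc20 in glia, and Rrm2 (0.52) and Tipin (0.37) in blood endothelium. The cause was not tested.

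Single-stage epithelial comparisons gave 1 gene at E14.5 (Blvrb, 2.24, known from red cells) and 3 at E18.5 (Aldh1a3 2.63, Fabp4 -4.16 and the hair keratin gene Krt35, 0 UMIs in males and 129 in females, ratio at most 0.0367), named after their values were seen; the interaction of sex with stage, E18.5 against E14.5, called 0 of 10177 genes in epithelium (507 at an unadjusted p of 0.05).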
